A study of Mus musculus with 2 samples.

How the data were processed

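Liver RNA was measured on 2 Affymetrix whole-transcript arrays, 1 for a control and 1 for an irradiated sample. Both samples came from male C57BL/6 mice, an inbred laboratory strain, at 9 weeks of age. Per the labels, irradiated mice received a single whole-body gamma dose of 6 Gy at 4 weeks of age, delivered at 0.81 Gy per minute, and liver RNA was taken 5 weeks later. The labels do not state whether each RNA came from 1 mouse or from a pool, nor how the control was handled during the irradiation. Total RNA was purified with a column kit, and 300 ng of it was converted to biotin-labelled cDNA, per the labels' protocols. Column kits of this kind recover very short RNAs incompletely.

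The deposited table held 1 log2 value per probe set and array, 41345 probe sets in all. Per the submitters' processing notes, the authors made these values with RMA in Affymetrix Expression Console 1.3.1. RMA corrects the background, normalizes the arrays to each other and summarises the probes of a probe set. The log base is not written in the file. The values ran from 1.46 to 13.9 on the control array and from 1.47 to 13.9 on the irradiated array, as log2 RMA values do, and every fold given here rests on that reading. The medians were 6.05 and 6.07, and the sorted values of the 2 arrays differed by at most 0.106. A difference in the total amount of RNA per cell cannot be seen in values normalized in this way. Scanner intensities and detection calls were not used here, and the array's genome build is not given in the sources used here, so no coordinates are given.

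Gene names came from GEO's annotation of the platform, which can be old. In it 23521 probe sets had 1 gene symbol, 1814 had several and 16010 had none. Genes were taken only from probe sets with exactly 1 symbol. The probe set with the highest mean of the 2 values stood for each of the 1082 genes with several probe sets, which left 22180 genes. Entrez identifiers of 21991 of them were found in the RefSeq gene table of mouse assembly GRCm38.p6, which was used only for gene classes. Probe sets with several symbols or none were summarised by counts, and values of a few of them, picked after they were seen, are also given.

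The measure was the log2 difference, irradiated minus control. A gene was counted as expressed when the higher of its 2 values reached 6.06, the median of all deposited values. This kept 13689 genes and left out 8491. The floor is a rank among all values, not a measured background. With 1 array per group there was no replicate and no test, so genes were counted by a fixed size of 2-fold, and no p-value was computed. The number of arrays limits the precision, and the spread between animals is unknown.

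Gene lists were read through their median difference over expressed members, with the number of members at least 1.5-fold higher or lower. Each median was placed among those of 10000 random lists of the same size, drawn from the same 20 bins of mean expression. A list was said to stand apart when its median lay outside the central 95% of these. Lists with under 5 expressed members got no percentile. The 40 lists covered damage and stress responses, liver metabolism, sex-biased genes, inflammation and the cell types a liver sample can hold. A further 27 symbol families were treated in the same way. About 2 of 40 lists would stand apart by chance if genes were independent. Genes of a list are often co-regulated, so the percentile describes these 2 arrays and is not a test of irradiation.

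The genes named were set by a rule. It took the 12 largest differences in each direction among expressed genes at least 2-fold different, leaving out predicted genes, clone names, small RNA symbols and receptor or immunoglobulin segments. It added up to 4 members of each list with the largest differences of at least 1.5-fold, and 17 genes fixed by name. Of these 17, 15 are reported here. Saa1, which had no probe set of its own in the annotation, was not analysed here. Members of near-identical families such as Cyp2b, Cyp3a, Saa and Ugt2b are named with the limit that probes can cross-hybridise. Genes named outside the rule are marked as such.

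The groups, the lists, the thresholds, this rule and most alternatives were fixed before the data were examined. The alternatives changed the expression filter, the scaling between arrays, the choice among probe sets, the size threshold, an added offset of 32 on the linear scale, the matching and the summary of the lists. The loess trend used a span of 0.3. The procedure was tested on simulated arrays of 22180 genes with noise of SD 0.2. There, 100% of genes changed by 2 log2 units and 7% of those changed by 0.75 were counted at 2-fold, and 0 unchanged genes were. All 20 lists of 25 genes shifted by 0.25 stood apart, as did 3% of 200 unshifted lists. The 0 unchanged genes follow from setting noise that small against a cut of 1 log2 unit. They give no rate of false calls on the real arrays, where differences of expressed genes had an SD of 0.229. The simulation checks the procedure only, since the spread between animals is unknown. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.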

Results

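The liver transcriptome of a male C57BL/6 mouse sample 5 weeks after 6 Gy of whole-body gamma irradiation was set against that of an age-matched control, with 1 array in each group. The comparison asks which liver transcripts differ weeks after a single exposure given at 4 weeks of age. There was no replicate, so none of the differences below has a replicate check. Values are log2 RMA values, and differences are irradiated minus control.

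Dmbt1, a mucosal scavenger receptor, had the largest of the 12 higher differences named by rule. It read 5.17 on the control array and 10.83 on the irradiated array, a difference of 5.66. The control value lay below the expression floor, and the difference was 50.5-fold as measured and 27.3-fold against the floor. The mucin gene Muc1 was 6.14-fold higher (2.62), and the epithelial surface gene Cd24a 5.65-fold (2.50), while its second probe set was below the floor on both arrays. Ctrb1, a pancreatic digestive protease, was 6.28-fold higher (2.65). The smooth muscle genes Cnn1 and Acta2 were higher by 2.42 and 1.97, folds of 5.37 and 3.92. A further 4 genes among the 12 were also below the floor in the control, so that their folds are given against the floor. They were the mucin gene Muc3 at 6.13-fold, the adhesion receptor gene Adgrg7 at 4.80-fold, Reg1, a secreted lectin of the pancreas and gut, at 4.36-fold, and the glycosyltransferase gene B4galnt2 at 2.48-fold.

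The other 2 of the 12 were stress-responsive genes. Egr1, an immediate early transcription factor, was 4.83-fold higher (2.27), and Gadd45g, a growth arrest and stress gene, was 3.32-fold higher (1.73). Fewer named genes were lower. Cyp2b9, a cytochrome P450 more abundant in female mouse liver, was below the floor on the irradiated array, at 5.62 against 8.18, a difference of -2.56 and 4.36-fold against the floor. Hamp2, a copy of the hepcidin gene, differed by -1.62, while Hamp itself differed by -0.06. Depp1, a FoxO-regulated gene, differed by -1.55, and the P450 gene Cyp3a25 by -1.28. Nr0b2 encodes SHP, a repressor of bile acid synthesis, and differed by -1.16. The water channel gene Aqp8 differed by -1.10 and the glycerophosphodiesterase gene Gpcpd1 by -1.03. These 7 were all the lower genes open to naming.

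**Figure D1:**
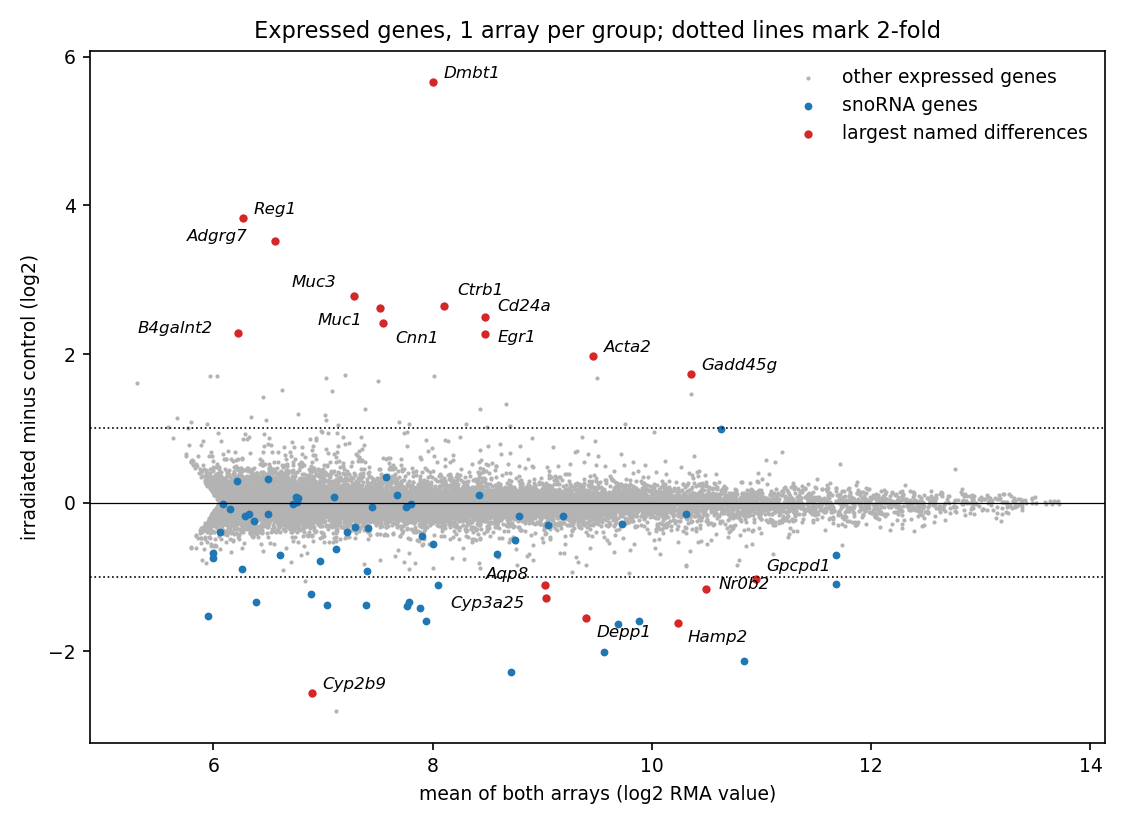
Log2 difference (irradiated minus control) of each expressed gene against the mean of its values on both arrays, 1 array per group, with snoRNA genes in blue, the largest named differences in red and dotted lines at 2-fold. Dmbt1 lies highest at 5.66, Cyp2b9 is the lowest named gene at -2.56, and 47 of the 57 snoRNA genes lie below 0.

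In all, 44 expressed genes were at least 2-fold higher and 25 at least 2-fold lower, 0.504% of 13689. Protein-coding genes made up 40 of the 44, but 7 of the 25. Of the lower genes, 16 were small nucleolar RNA genes, whose products guide chemical modification of ribosomal RNA. Of the 44, 17 were below the floor in the control, and 34 were 2-fold higher when values below the floor were set to it, an alternative added after seeing the data. Across expressed genes the 2 arrays had a Pearson correlation of 0.990, where genes are not independent replicates. The median difference was -0.00, and the central 95% of genes lay between -0.37 and 0.42.

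The p53 targets were higher as a group, with 19 of 26 expressed members above 0 and a median of 0.13 (percentile 99.99 among random lists). Members at least 1.5-fold higher numbered 4, and 0 were as much lower. Cdkn1a, the p21 inhibitor of the cell cycle, was 3.26-fold higher, from 7.16 to 8.87. Btg2, an antiproliferative gene, was higher by 1.05, the stress kinase gene Plk3 by 0.68 and the mTOR inhibitor gene Ddit4 by 0.60. Mdm2, which encodes the ligase that degrades p53, differed by 0.03, and Ccng1 by 0.16. DNA repair genes lay inside the random range with a median of -0.03 over 29 members, none of them 1.5-fold different. Cell cycle genes had a median of 0.13 over 26 members (percentile 99.8), and 0 reached 1.5-fold, with Mki67, a proliferation marker, at 0.25. The list lay inside the random range with the floor at the 75th percentile (0.090). The 16 senescence and secretory genes had a median of 0.08, inside the random range, but their mean of 0.24 lay outside it.

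Immediate early genes were the second most displaced list, with a median of 0.25 over 27 members, 23 above 0 and 6 at least 1.5-fold higher. Besides Egr1, the transcription factor genes Myc and Fos were 3.20-fold and 2.84-fold higher. The list of unfolded protein and integrated stress response genes had a median of 0.14 over 27 members, with 5 at least 1.5-fold higher and 0 lower. These included the transcription factor gene Atf3 at 1.03, Nupr1 at 0.65, the endoplasmic reticulum gene Creld2 at 0.62 and the asparagine synthetase gene Asns at 0.61. Heat shock genes had a median of 0.12 over 17 members and Nrf2 targets, the oxidative stress list, 0.07 over 22. In neither did any member reach 1.5-fold. Heat shock genes lay inside the range when means were used (0.076), and Nrf2 targets did with unmatched random lists or without genes shared between lists (0.050).

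Bile duct markers were the most displaced list. All 15 expressed cholangiocyte genes were above 0, with a median of 0.38, and 6 were at least 1.5-fold higher. Beside Muc1 and Cd24a, the duct keratin gene Krt19 was higher by 1.20 and the epithelial annexin gene Anxa13 by 1.12. Genes of other organs had a median of 0.14 over 14 members, where Ctrb1 and the gut lectin gene Lgals4 (1.06) were the 2 members past 1.5-fold. That list lay inside the random range when low genes were kept (0.054) or the first of several symbols was used (0.090). Matrix and fibrosis genes had a median of 0.14 over 30 members, 26 above 0. Of these, 5 were at least 1.5-fold higher, among them Acta2, Thbs1 (0.79) and Postn (0.75), while Col1a1 was at 0.27. The macrophage elastase gene Mmp12 was another, below the floor in the control and 1.60-fold higher against it. The stellate cell list as a whole had a median of 0.00, although its members Acta2 and Des (0.95), both also smooth muscle genes, were higher. It stood apart by its mean (0.15) and with the floor at the 75th percentile (0.067). Hepatocyte markers had a median of -0.00 over 17 members, and Alb differed by 0.01.

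Kupffer cell and macrophage markers had a median of 0.13 over 26 members, 21 above 0. The lipopolysaccharide receptor gene Cd14 was higher by 0.65 and Gpnmb by 0.63, and both were below the floor in the control. Against the floor they were 1.28-fold and 1.16-fold higher, short of 1.5-fold. Acute phase genes had a median of 0.09 over 24 members, 19 above 0. The iron-binding Lcn2 was higher by 1.08, the cytokine signalling inhibitor gene Socs3 by 0.84 and the serum amyloid gene Saa2 by 0.68, while Orm3 was lower at -0.83. The second probe set of Socs3 was below the floor on both arrays. A probe set annotated with both Saa1 and Saa2 was higher by 0.42, short of 1.5-fold. NF-kB targets had a median of 0.10 over 24 members, with none past 1.5-fold, and complement and coagulation genes 0.05 over 31. NF-kB targets lay inside the random range with the floor at the 75th percentile (0.051), with means, or without genes shared between lists (0.069), and complement genes with unmatched random lists. Interferon-stimulated genes (0.01 over 27) and antigen presentation genes (0.03 over 16) lay inside the random range. So did B cell markers (-0.06 over 12), T and NK cell markers (0.01 over 10), neutrophil markers (-0.08 over 7) and endothelial markers (-0.05 over 29, with Cd34 at 0.60). Erythroid markers had a median of 0.11 over 11 members, also inside the range except without genes shared between lists (0.15), with the carbonic anhydrase gene Car2 at 0.88. Probe sets annotated with several globin genes did not enter that median, and all 5 were lower, with the 2 above the floor at -1.10 and -0.17.

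**Figure D2:**
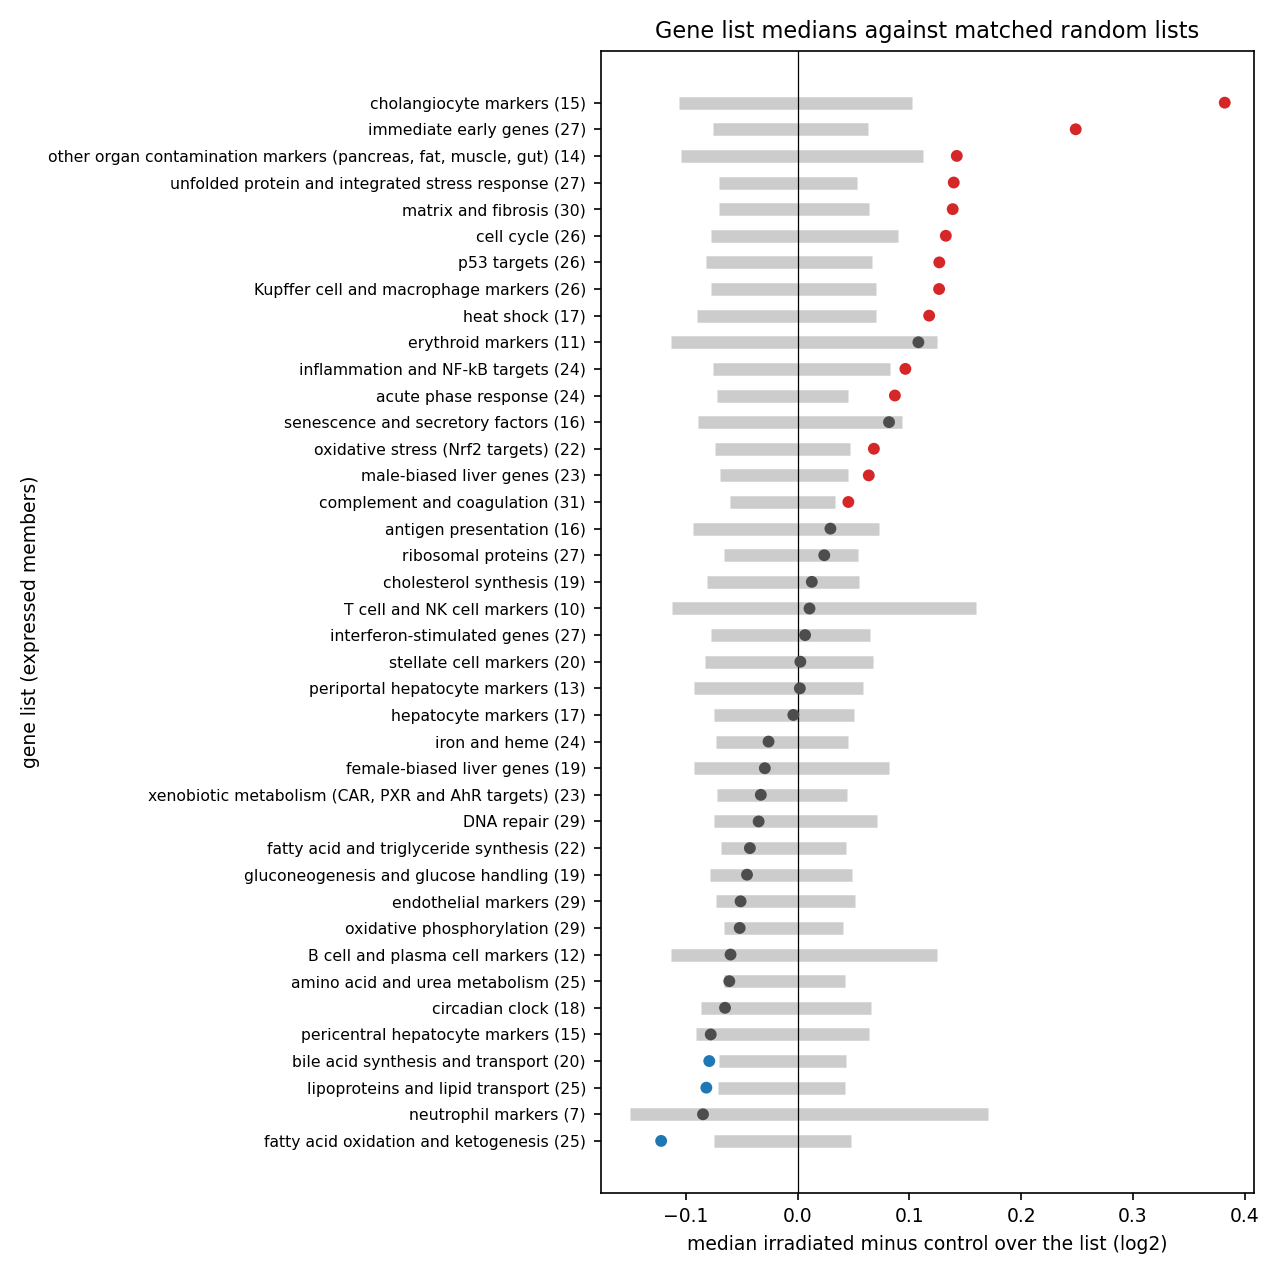
Median log2 difference (irradiated minus control) of each of 40 gene lists, with the number of expressed members in brackets. Grey bars span the central 95% of 10000 random lists matched on expression, and points outside them are red (14 lists, higher) or blue (3 lists, lower). Cholangiocyte markers lie farthest right at 0.38 and fatty acid oxidation genes farthest left at -0.12.

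Of the 40 lists 14 stood apart higher and 3 lower, and the 3 lower ones were metabolic. Fatty acid oxidation and ketogenesis genes had a median of -0.12 over 25 members, 6 of them above 0 (percentile 0.03). Among them Vnn1, a pantetheinase and PPARalpha target, was at -0.63 and the fatty acid hydroxylase gene Cyp4a14 at -0.56. Lipoprotein and lipid transport genes had a median of -0.08 over 25 members, with Angptl4, an inhibitor of lipoprotein lipase, at -0.80. Bile acid synthesis and transport genes had a median of -0.08 over 20 members. In that list Nr0b2 and the organic anion transporter gene Slco1a4 (-0.66) were past 1.5-fold, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -0.23. The bile acid list lay inside the range when low genes were kept (-0.065) or random lists were not matched on expression.

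Other metabolic lists lay inside the random range. Cholesterol synthesis (0.01), fatty acid and triglyceride synthesis (-0.04), gluconeogenesis (-0.05), xenobiotic metabolism (-0.03), iron and heme (-0.03) and amino acid and urea metabolism (-0.06) were among them. Oxidative phosphorylation (-0.05) and ribosomal protein genes (0.02, with Rps15 at -0.65) were too. Scd1, a lipogenic desaturase, differed by -0.05, Pck1, which encodes a gluconeogenic enzyme, by 0.06, Cyp3a11 by 0.04 and Cyp2b10 by -0.45. Pericentral hepatocyte markers had a median of -0.08 over 15 members, with the transcription factor gene Tbx3 at -0.71, and periportal markers 0.00 over 13. By their means, xenobiotic metabolism genes (-0.11) and pericentral markers (-0.13) stood apart lower. Cyp3a25, at -1.28, was the only xenobiotic member past 1.5-fold and weighed most in that mean. Ribosomal protein genes stood apart higher with the floor at the 75th percentile (0.052). Clock genes had a median of -0.06 over 18 members, with the activator gene Arntl at 0.61 and the output gene Dbp at -0.39.

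Sex-biased genes went different ways by gene. Male-biased genes had a median of 0.06 over 23 members, with 1 past 1.5-fold, the glucuronosyltransferase gene Ugt2b38 at 1.06. The list lay inside the range with unmatched random lists or without shared genes (0.015). Female-biased genes had a median of -0.03 over 19 members, inside the range, while their mean of -0.19 lay outside it. Cyp2b9, at -2.56, weighed most in that mean. Besides Cyp2b9, the peroxisomal transporter gene Abcd2 was lower at -0.68, whereas Cyp2c40 was higher at 0.71 and Prom1, also a bile duct marker, at 0.69.

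**Figure D3:**
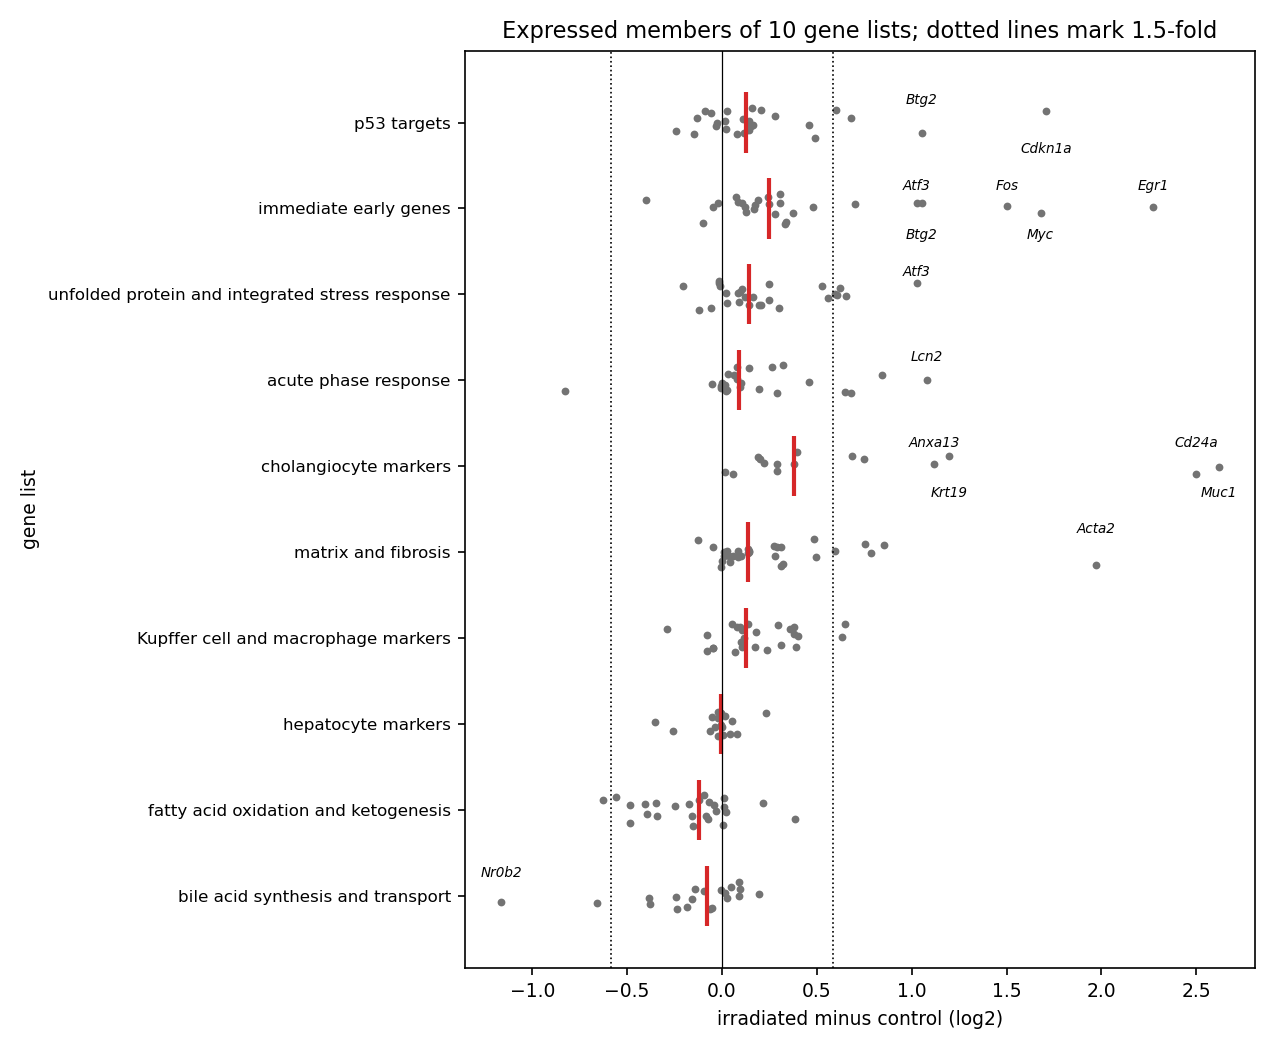
Log2 difference (irradiated minus control) of each expressed member of 10 gene lists, with a point per gene, a red bar at the list median and dotted lines at 1.5-fold. Points are spread vertically only for legibility, and names mark members beyond about 1 log2 unit. The cholangiocyte median of 0.38 lies farthest right, and hepatocyte markers centre on -0.00.

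Small nucleolar RNA genes were lower as a group, and Snord was the most displaced symbol family. Snord genes had a median of -0.58 over 34 expressed members, 17 of them at least 1.5-fold lower, and Snora genes -0.29 over 23, 8 of them lower. Together 47 of 57 were below 0 (82.5%), and 1 was 1.5-fold higher. Genes with the symbol prefix Mir, nearly all microRNA genes, lay inside the random range (0.04 over 114), though outside it after loess or quantile scaling.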

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

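No test of an explanation was made for the values below, which were singled out after they were seen.

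The comparisons by gene leave out probe sets that the annotation gives no symbol, and signal differed there too. Among 6343 such probe sets above the expression floor, 82 were at least 2-fold higher on the irradiated array and 64 at least 2-fold lower. The higher ones made up 1.29% of them, against 0.321% of expressed named genes, and the lower ones 1.01% against 0.183%. These shares are not like for like. Unnamed probe sets were counted singly, some with identical values, while each named gene was counted once. Many of the unnamed ones past 2-fold have identifiers in the block from 17200167 to 17210711. Whether an unnamed probe set measures a transcript or is a control of the array was not looked up here. Of the 82, 62 were below the floor in the control, and of the 64, 30 were below it on the irradiated array. With values below the floor set to it, 31 were 2-fold higher and 41 were 2-fold lower. The largest higher difference was 3.04, for probe set 17514340, which was above the floor on both arrays. Probe set 17514340 lies within a stretch of 11 consecutive unnamed probe sets of the file, all at least 2-fold higher as measured. On the irradiated array 10 of them reached the floor, and 5 of these 10 were below it in the control, so that 8 were 2-fold higher against the floor. What these probe sets measure is not known here. Of 989 expressed probe sets with several symbols, 0 were 2-fold higher and 28 were 2-fold lower. These 28 held 12 distinct pairs of values, and 16 of them shared a single pair. The 16 carry the snoRNA symbols Snord116l1 and Snord116l2 with Gm26504, and 7 others carry Gm3893, taken up below. Further ones carry Snord68, Snord34 or Snord32a with a ribosomal protein gene, and the rest carry Hba or Raet1 symbols. Most of the 28 therefore go with the lower snoRNA and Gm3893 values given elsewhere.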

How the results depend on the processing

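Leaving out non-coding genes, leaving out genes of bile duct, smooth muscle and other organs, and setting values below the floor to it were alternatives chosen after seeing the data. Running the symbol families under the other scalings was not planned beforehand either. No paired analysis was possible because each group held 1 array. No named gene at least 1.5-fold different, and no list or symbol family that stood apart, reversed its direction under any alternative run for it. Lists inside the random range were not followed for direction, and some changed sign. Neutrophil markers had a median of -0.08 and a mean of 0.05, and ribosomal protein genes 0.02 and -0.01. Of the gene list values for lists that stood apart, 221 stayed outside the random range and 14 did not. All were reruns of the same 2 arrays, and some, such as centring, hardly changed the values, so the count does not measure support. Fewer genes were counted as 2-fold higher when the floor was the 75th percentile of all values (28), when 32 was added on the linear scale (27) or at 3-fold (20), and more at 1.5-fold (156). The lower genes numbered 9 at 3-fold, 89 at 1.5-fold and 7 when only protein-coding genes were kept, since most of the others were snoRNA genes. With values below the floor set to it, 34 genes were 2-fold higher and 24 lower, and 14 lists stood apart higher and 3 lower. Leaving out the genes of bile duct, smooth muscle and other organs was no test of the lists, since it emptied the lists of bile ducts and other organs, and it spared Dmbt1 and Cnn1. With means in place of medians, 6 lists stood apart lower. Lists came to lie inside the random range as follows, and the cause was not tested. With no filter, bile acid genes (-0.065) and genes of other organs (0.054) did. With the 75th percentile floor, cell cycle genes (0.090) and NF-kB targets (0.051) did. With the first of several symbols, genes of other organs (0.090) did. With unmatched random lists, bile acid genes (-0.079), male-biased genes (0.064), Nrf2 targets (0.068) and complement genes (0.045) did. With means, NF-kB targets (0.10) and heat shock genes (0.076) did. Without genes shared between lists, male-biased genes (0.015), Nrf2 targets (0.050) and NF-kB targets (0.069) did. Other lists came to stand apart. With means, senescence (0.24), stellate cell (0.15), female-biased (-0.19), xenobiotic (-0.11) and pericentral genes (-0.13) did. With the 75th percentile floor, ribosomal protein (0.052) and stellate cell genes (0.067) did, and without shared genes erythroid genes (0.15) did. So did the Mir family after loess (0.047) or quantile scaling (0.038), and the Ugt family after quantile scaling (0.072). Named genes were followed under the filters, the scalings, the probe set choices and with values below the floor set to it. Of these genes 3 moved to the other side of 1.5-fold. Socs3 did, at 0.52 with the mean of its probe sets, the second of which was below the floor on both arrays. Cd14 (0.35) and Gpnmb (0.22) did with values below the floor set to it. No scaling moved the median of all genes by over 0.1. Genes near the floor have a low signal, and no measured background was used here.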

Other observations

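Among the tests below, those of acute stress, of short RNA recovery and of dim probe sets were chosen after the result was seen, and the lists for gallbladder, smooth muscle, pancreas and snoRNA hosts were written after the largest differences were seen. The genes named here outside the naming rule were chosen after their values were seen.

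Several symbol families differed as groups, with small medians. Ifi genes, an interferon-inducible group, had a median of 0.29 over 8 members, 7 above 0, with Ifi205 at 0.69 and Ifi204 at 0.36. Gbp genes, interferon-inducible GTPases, went the other way, with a median of -0.31, 0 of 6 members above 0 and Gbp11 lowest at -0.77. The prefix Ifit, inside the random range, took in 3 Ifit genes, Ifit1 (0.14), Ifit2 (0.13) and Ifit3 (0.39), and 4 Ifitm genes, all below 0. Glutathione transferase genes had a median of -0.14 over 16 members, with Gstt3 at -0.73 and Gstt2 at -0.57. Sulfotransferase genes had a median of -0.16 over 6 members, with Sult1b1 at -0.68, and Cyp2 genes -0.06 over 36. Of the 11 expressed glucuronosyltransferase genes, Ugt2b37 (1.72) and Ugt2b38 (1.06) were past 1.5-fold, and the family lay inside the random range, though outside it after quantile scaling.

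Transcripts of the predicted gene Gm3893 were lower on all 3 of its own probe sets, at -1.92, -2.83 and -2.81, with all 3 values on the irradiated array below the floor. Of 13 probe sets it shares with other symbols, 7 were at least 2-fold lower and another was at -0.98. The rest, with differences up to 0.23, were below the floor on both arrays. Single snoRNA genes with the lowest values were Snord35a (-2.28), Snord89 (-2.13) and Snord99 (-2.01), while Snora44 was higher at 0.99. The ion transporter genes Slc26a3 and Slc9a3, known from intestinal epithelium, were below the floor in the control and higher by 0.83 and 0.87 against it. The carbonic anhydrase gene Car4 was also below the floor in the control and higher by 1.10 against it, and the transcription factor gene Klf5 was higher by 1.26.

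The higher mucosal and smooth muscle genes may come from extrahepatic biliary tissue, such as gallbladder wall, in the irradiated sample. Gut tissue was not tested as a source, although Lgals4, Slc26a3 and Slc9a3, named above with the gut or intestine, were also higher. The 2 lists used here leave out the 12 higher genes named by rule. Gallbladder epithelium had a median of 0.22 over 23 members and visceral smooth muscle 0.27 over 17, both at percentile 100 of random lists. Some members were still large, with 4 and 3 at least 1.5-fold higher. Myl9 was at 0.85, Actg2 at 0.84, Wfdc2 at 0.62 and Krt8 at 0.20, where Krt8 already read 11.1 in the control. Both lists were written after the largest differences were seen and can hold genes co-regulated with them. Their percentiles are therefore not independent support. Of the listed genes on the array, 22 of 37 and 15 of 19 were at or above the floor in the control liver too, 8 of the 23 also stand in the cholangiocyte list, and the remaining 15 had a median of 0.20, while Agr2 (0.00) and Krt20 (0.17) stayed below the floor. Pancreatic tissue is argued against by 23 acinar genes, a list without Ctrb1 and Reg1, with a median of -0.074. Cela3b was at 0.06 and Cpa1 at 0.02, although only 7 of the acinar genes were above the floor (0 of them 1.5-fold higher). Growth of ducts alone would leave the smooth muscle median of 0.27 unexplained. That list was written after Cnn1 and Acta2 were seen to be higher, so its median is no independent test of such growth. A ductular reaction with myofibroblasts after irradiation remains open, since 1 sample per group cannot separate tissue sampling from the exposure.

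The lower snoRNA values could reflect the host transcripts, the recovery of short RNAs or noise. Host genes had a median of -0.040 over 31 members, Snhg17 (-0.84) having been seen beforehand, against -0.39 for all 57 snoRNAs, which argues against a general loss of hosts, though hosts were not matched to each snoRNA. The brighter 29 snoRNAs had a median of -0.50, which argues against noise of dim probe sets. Recovery cannot be told apart from irradiation: other short RNA genes had a median of 0.035, and the bound first set for excluding recovery, a median of 0 or more, was met. That bound was dropped after the values were seen, because 114 of the 128 are microRNA genes so that the median speaks for microRNAs, and the 14 others had a median of -0.20.

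For Cdkn1a and the immediate early genes, lasting p53 activity, acute stress around collection and a different time of day were set side by side. A different tissue make-up of the irradiated sample, raised above, was not tested for these genes. With 1 sample per group it cannot be told apart from the exposure. The p53 targets without Cdkn1a and immediate early genes had a median of 0.11 over 24 members (percentile 99.8), with 17 above 0. Plk3 and Ddit4 were the 2 members past 1.5-fold, while Mdm2 was at 0.03, Phlda3 at 0.08 and Perp at -0.24. The median goes with p53 activity but is not particular to it, since 14 of the 40 lists stood apart higher, cell cycle genes among them. Acute stress stays open, since the heat shock median of 0.12 stood apart but no member reached 1.5-fold and the mean of 0.076 lay inside the random range. A different time of day cannot be told apart from these: 1 of 11 core clock genes differed by 1.5-fold, which met the bound first set for excluding it. That bound was set aside after the values were seen, because Nr1d1 at -0.54 lies just inside it and opposes Arntl at 0.61, as in a shift in phase. These were the only 2 of the 11 to reach 1.4-fold, so the values neither show nor exclude a small shift.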
